A study of Mus musculus with 2 samples.

How the data were processed

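Stage 1 iNKT cells were stained with surface antibodies and sorted from the thymus of C57BL/6 mice aged 5 weeks on an Aria II instrument, lysed in Trizol, and made into libraries with the TruSeq RNA kit, per the labels' protocols. There were 2 libraries, 1 wild type and 1 Uhrf1 KO, grouped by the genotype in the labels. The number of mice behind each library, the gate and the way Uhrf1 was deleted are not given in the sources used here. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks 2.1.1 and the mm10 build were used; the role of each tool, the annotation and the filters are not given in the sources used here.

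For each gene the authors deposited an FPKM value, per the file headers, a unit that corrects fragments for transcript length and for the size of the library. Beside it stands a column that the file headers call a count. These deposited values behave as a scaled signal and not as raw counts: most are whole multiples of 0.799 in the wild type and 1.70 in the KO, and both columns sum to nearly the same total. They were divided by these steps to give reads per gene. Within 0.01 of a read, or the rounding of the files' digits for large values, 98.2% of nonzero genes were whole in the wild type (12140 of 12358) and 98.7% in the KO (11297 of 11442). Fractions remained for the rest, so no count model was fitted. The assumption written beforehand was FPKM alone, and the FPKM scale was kept as the main one.

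The files held 16386 genes, 3125 of them at 0 reads in both libraries. Depth was 26005836 reads in the wild type and 12189861 in the KO. Of 23 symbols that had been turned into dates, 19 were named by position. Entrez identifiers of 16327 genes matched the RefSeq table of GRCm38.p6, the assembly also called mm10, which gave the 1-based gene coordinates printed here. In the files a locus can span several genes, and 2696 genes shared theirs with another; where strand was not used, their reads cannot be told apart. Such genes named below include Rptor, Mlst8, Cdc20, Rora, Nnat, Snrpn, Arpp21, Zbtb38, Hba-a1, Rpl26, Macrod1 and Foxp3.

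The measure was log2((KO FPKM + 1) / (WT FPKM + 1)), which understates the change of low genes. Genes with a mean FPKM of at least 1 were measured (9955), and a change was counted when its log2 ratio was at least 1 in size. A gene's fold was the ratio of scaled counts, with a 95% Clopper-Pearson interval from its reads in both libraries. Where a library had 0 reads, the fold was a lower bound against a floor of 3 reads per library. Before the data were examined, 36 gene lists were fixed; 1054 of their 1153 names were found, 10 of them by synonym. The median of each list with at least 4 measured members was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A list was called apart below percentile 2.5 or above 97.5. After the data were seen, the pick among lists was also allowed for: each of 10000 draws took a random list for each of the 33 lists and kept the largest departure, in SDs of that list's random medians. Percentiles describe these libraries and are not tests of the genotype.

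The genes named were also set by a rule fixed beforehand: Uhrf1, the 4 transporters in the study's design text, the 10 largest rises and 10 largest falls at a mean FPKM of at least 5 without predicted, segment, histone, ribosomal, small RNA and mitochondrial genes, up to 4 members of each list with the largest change, and a fixed set of well known members. This gave 154 genes. A few of them are not reported here. Names outside it are said to be chosen after their values were seen.

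The steps were tested on simulated data for the KO against the wild type, on 9955 genes with counting error alone. Of 50 genes given a 4-fold rise 50 passed the size rule, and of 50 given a 4-fold fall 42 did (84%). The share required of falls was lowered after that 84% was seen, because the pseudocount shrinks falls of genes near an FPKM of 1. At a 2-fold change, which lies on the rule itself, 13 of 50 rises and 9 of 50 falls passed. Of 9755 unchanged genes 2 passed. Lists of 20 genes shifted by 0, 0.5 and 1 were found apart on the high side in 1, 34 and 86 of 100 draws.

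The alternatives planned were 11: a pseudocount of 0.1 or 5, no filter, a mean FPKM of at least 5, rescaling to a median ratio of 0, to the upper quartile or to the sum without the 50 most abundant genes, removal of a lowess trend, the highest row per symbol, and size rules of 2 and 0.5. After the data were seen 3 were added: more than 10 reads in each library, a mean FPKM of at least 25, and 5 lists without members they share with other lists. A planned filter on the status and confidence limits of each estimate was not run, as the columns used here do not include them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.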

Results

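RNA was sequenced from stage 1 invariant natural killer T (iNKT) cells of the mouse thymus, an early step of a T cell lineage that carries a semi-invariant T cell receptor. The cells came from C57BL/6 mice aged 5 weeks. One group was wild type and the other was a knockout (KO) of Uhrf1, the protein that brings the maintenance methyltransferase Dnmt1 to newly copied DNA. Each genotype had 1 library, so no difference given here has a replicate check and no p-value was computed. The wild-type library held 26005836 reads assigned to genes and the KO library held 12189861. At FPKM of at least 1, 9504 genes were seen in the wild type and 8884 in the KO. The comparison asks which genes differ between the genotypes, with the stated interest in nutrient transporters and in the Akt-mTOR pathway. Here "rose" and "fell" mean a change of at least 1 in log2((KO FPKM + 1) / (WT FPKM + 1)). Folds come from the scaled counts, and their 95% exact intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

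Uhrf1 itself (Entrez gene 18140, chromosome 17, 56303337 to 56323486 in mm10) fell from an FPKM of 35.3 in the wild type to 0.626 in the KO. Its reads numbered 3032 and 25, which is 56.8-fold lower in the KO (interval 38.4 to 88.0). Of 755 genes with a wild-type FPKM near that of Uhrf1 (28.2 to 44.1), 25 (3.31%) fell at least as far. Both numbers include Uhrf1 itself. Which part of the gene was deleted was not analysed here.

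**Figure D1:**
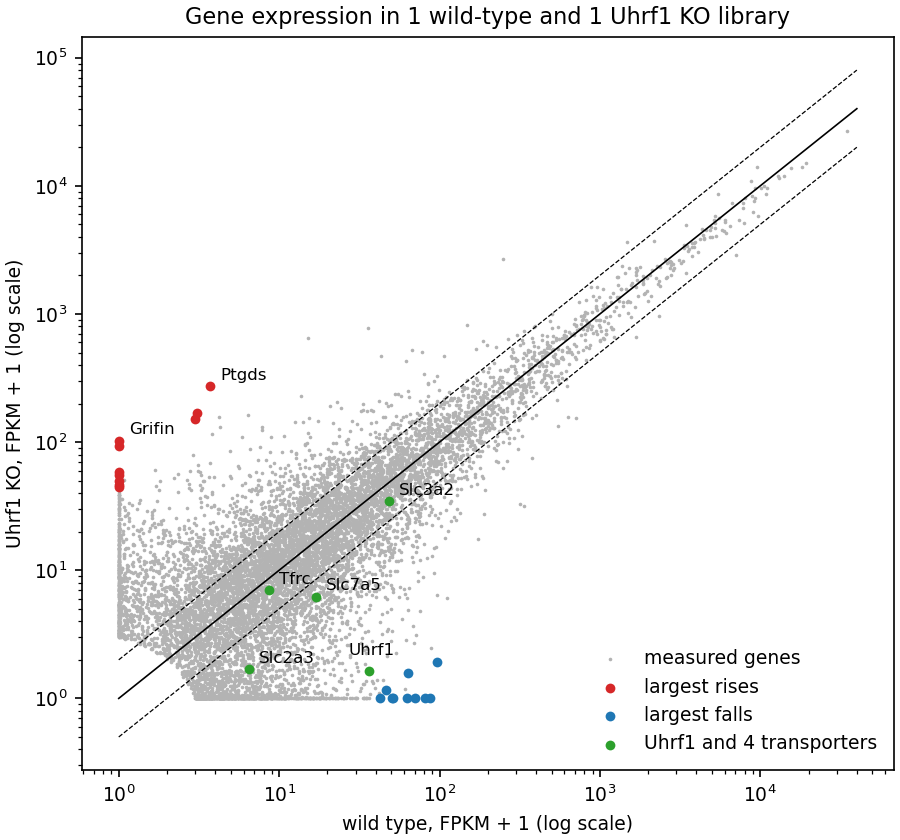
Each grey point is 1 of the 9955 measured genes, with FPKM + 1 in the wild-type library on the x axis and in the Uhrf1 KO library on the y axis, both on log scales. The solid line marks equal values and the dashed lines a 2-fold difference; red and blue points are the 10 largest rises and falls, and green points are Uhrf1 and the 4 transporters, of which Slc3a2 and Tfrc lie between the dashed lines.

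Across the transcriptome the libraries differed widely. Of 9955 genes with a mean FPKM of at least 1, 2116 rose in the KO and 2354 fell, together 44.9% of those measured. The change reached 4-fold on the same scale for 851 genes that rose and 1026 that fell. The log2 ratios had a median of -0.0048 and an SD of 1.58 across genes. The share past the size rule was 61.1% at a mean FPKM of 1 to 5, 47.3% at 5 to 25, 32.3% at 25 to 100 and 13.7% at 100 or more. The spread was far above the counting error of these depths, and 300 genes with an FPKM of at least 5 in the wild type had 3 reads or fewer in the KO, against 218 in the other direction. Without a second library per genotype, the part of this spread that belongs to Uhrf1 cannot be separated from differences between single preparations.

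**Figure D2:**
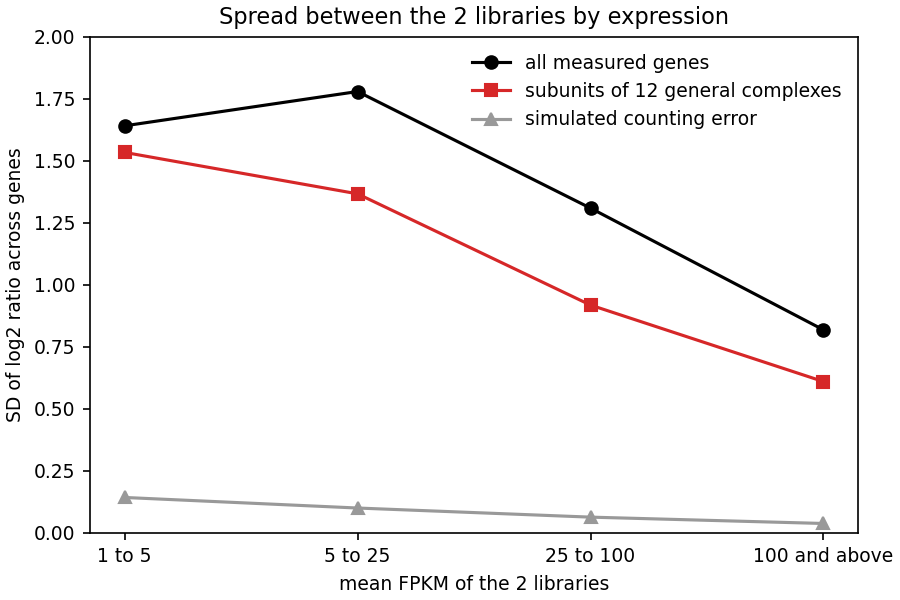
The y axis gives the SD of log2 ratios across genes in 4 bins of mean FPKM on the x axis, for all measured genes (black), for subunits of 12 general complexes (red) and for ratios simulated from counting error alone (grey). The SD of all genes ran from 1.64 in the lowest bin to 0.82 in the highest, and the simulated SD from 0.14 to 0.038.

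The 4 transporters named by the study all had lower values in the KO, and 2 of them fell. Slc2a3, a glucose transporter (chromosome 6, 122727809 to 122802363), fell from an FPKM of 5.46 to 0.701, 7.71-fold by scaled counts (interval 5.62 to 10.8). With a pseudocount of 5 its log2 ratio was -0.88, short of the size rule. Slc7a5, the light chain of the large neutral amino acid transporter (chromosome 8, 121881146 to 121907686), fell from 15.9 to 5.23, 3.17-fold (interval 2.71 to 3.72). Its heavy chain Slc3a2 (chromosome 19, 8706882 to 8723369) had 47.4 and 33.4, and the transferrin receptor Tfrc (chromosome 16, 32608896 to 32632794) had 7.63 and 5.96. The study chose these genes on these samples, so their count is not independent evidence of a direction. Their median log2 ratio of -0.97 lay at percentile 13.1 of 10000 random lists matched on expression, inside the range of chance lists.

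Genes of the Akt-mTOR pathway moved both ways. Of 37 measured components, 8 rose and 8 fell, and the median of -0.33 lay at percentile 8.82, within the random range. Rptor, the subunit of mTORC1 that recruits substrates, fell from 6.41 to 0.618, and Mlst8, shared by both mTOR complexes, from 6.14 to 0.0888 (3 reads in the KO, ratio 72.8, interval 24.8 to 354). Rptor and Mlst8 each share their locus with another gene. Mtor had 2.53 and 1.65, and Akt1 had 95.9 and 93.6. Sesn1 rose from 1.36 to 11.0, and Sesn2, an inhibitor of mTORC1 induced by amino acid shortage, rose from 0 to 8.71, at least 127-fold. Among 39 mTORC1-induced genes 6 rose and 12 fell, with a median of -0.19 at percentile 13.2. Phgdh, the first enzyme of serine synthesis, fell from 316 to 32.0. All 4 study transporters are also members of that list.

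Metabolic lists stayed inside the random range as well. Of 26 glycolysis genes 5 rose and 6 fell (median -0.26, percentile 12.4). Slc16a3, a lactate exporter, fell from 8.07 to 0.69, while Aldoc rose from 1.35 to 39.8 and Eno2 from 0.44 to 10.7. The glucose transporter Slc2a1 rose from 0.091 to 3.78 on 5 and 95 reads (log2 ratio 0.79 with a pseudocount of 5), and Hk2 had 0.348 and 0.507. Of 27 sterol synthesis genes 5 rose and 4 fell (median 0.22, mean -0.038, percentile 78.5). Mvd fell from 21.6 to 0.158, while Insig2 rose from 7.17 to 25.3. Among 75 oxidative phosphorylation genes 3 rose and 5 fell (median 0.02, mean -0.10, percentile 75.4). Sdhd fell from 96.2 to 24.5.

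Genes of growth and of the later cell cycle were lower in the KO as groups. Of 46 MYC and ribosome biogenesis genes 11 fell and 2 rose, and the median of -0.38 lay at percentile 0.25. Myc fell from 37.7 to 18.3, 2.06-fold (interval 1.86 to 2.27; log2 ratio -0.88 with a pseudocount of 5), Mybbp1a from 69.4 to 24.4 and Prmt3 from 23.5 to 1.93. Of 50 G2/M and mitosis genes 18 fell and 4 rose (median -0.49, percentile 0.96). Cdc20 fell from 49.5 to 2.38, Plk1 from 16.1 to 1.10, and the mitotic kinase Cdk1 from 9.95 to 0.0627 on 992 and 3 reads (ratio 155, interval 52.9 to 753). Mki67, the usual marker of cycling cells, had 30.0 and 22.2. The G2/M call ended among genes with a mean FPKM of at least 25, where the median was -0.14. Allowing for the number of lists, 2598 of 10000 draws held a departure as large as that of the MYC list. For the G2/M list 5153 draws did. Genes of naive T cells, a resting cell type, were higher in the same library (median 1.41, percentile 100), so a share of such cells in it is not ruled out as a source of these lower values and of the histone values given next.

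Replication-dependent histones, made mainly in S phase, were also lower as a group. Of 46 members 16 fell and 3 rose, and the median of -0.67 lay at percentile 0.03. Hist1h4d fell from 335 to 31.0 and Hist1h1a from 59.6 to 0.182. Histone genes are near-identical copies, so single members are uncertain. How well each preparation captured these transcripts was not tested, so a difference between the 2 preparations is not separated from the genotype. Of 45 G1/S and DNA replication genes 14 fell and 4 rose, with a median of -0.21 at percentile 10.5, inside the random range. Cdc45 fell from 46.4 to 2.49, Dscc1 rose from 1.05 to 29.8, and Pcna had 137 and 114. Of 80 cytoplasmic ribosomal protein genes 1 rose, Rpl26, and none fell. Their median of -0.19 lay at percentile 2.205, and removing a lowess trend on expression moved it to percentile 24.4. Ribosomal protein genes held 20.7% of wild-type reads and 17.2% of KO reads.

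The genes that define the iNKT lineage and its subsets did not move together. Zbtb16, which encodes the lineage factor PLZF (chromosome 9, 48651797 to 48836225), fell from 114 to 41.9, 2.81-fold (interval 2.69 to 2.93). Gata3 fell from 56.9 to 24.4, Il4 from 316 to 150, Icos from 247 to 62.0 and Il17rb from 72.8 to 8.61. Across all 35 early iNKT and NKT2 genes, though, 10 fell and 7 rose, and the median of -0.033 lay at percentile 33.7. Egr2, induced by the selecting receptor signal, had 12.8 and 13.99.

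NKT1 and stage 3 genes were higher as a group, with 13 of 26 risen and 7 fallen (median 0.93, percentile 99.96). Tbx21, which encodes T-bet (chromosome 11, 97098007 to 97115331), rose from 1.94 to 13.02, 6.33-fold (interval 4.96 to 8.14). Xcl1 rose from 1.33 to 55.5, Gzmb from 0 to 9.17 and Cd44 from 0.95 to 3.51. Other members went the opposite way: Gzma fell from 45.4 to 0.156, Klrb1c, which encodes NK1.1, from 4.42 to 0.135, and Il2rb from 61.2 to 26.5. With a pseudocount of 5 Cd44 (0.52) and Klrb1c (-0.87) were short of the size rule. The median stayed at 0.94 (percentile 99.9) over the 22 members not shared with the NK, myeloid or naive T cell lists. With no filter on low values the median was -0.025.

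NKT17 genes were lower, with 6 of 11 fallen and none risen (median -1.11, percentile 1.535). Maf fell from 46.4 to 1.13 and Rora from 10.8 to 0.28. The gamma-delta T cell list was lower still, with 4 of 6 members fallen and none risen. Its median of -3.85 lay below all 10000 random lists. Sox13 fell from 62.8 to 0.584 and Blk from 49.98 to 0, at least 451-fold. The lists share 3 measured genes, and the NKT17 median without them was -0.94, at percentile 6.75, inside the random range.

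**Figure D3:**
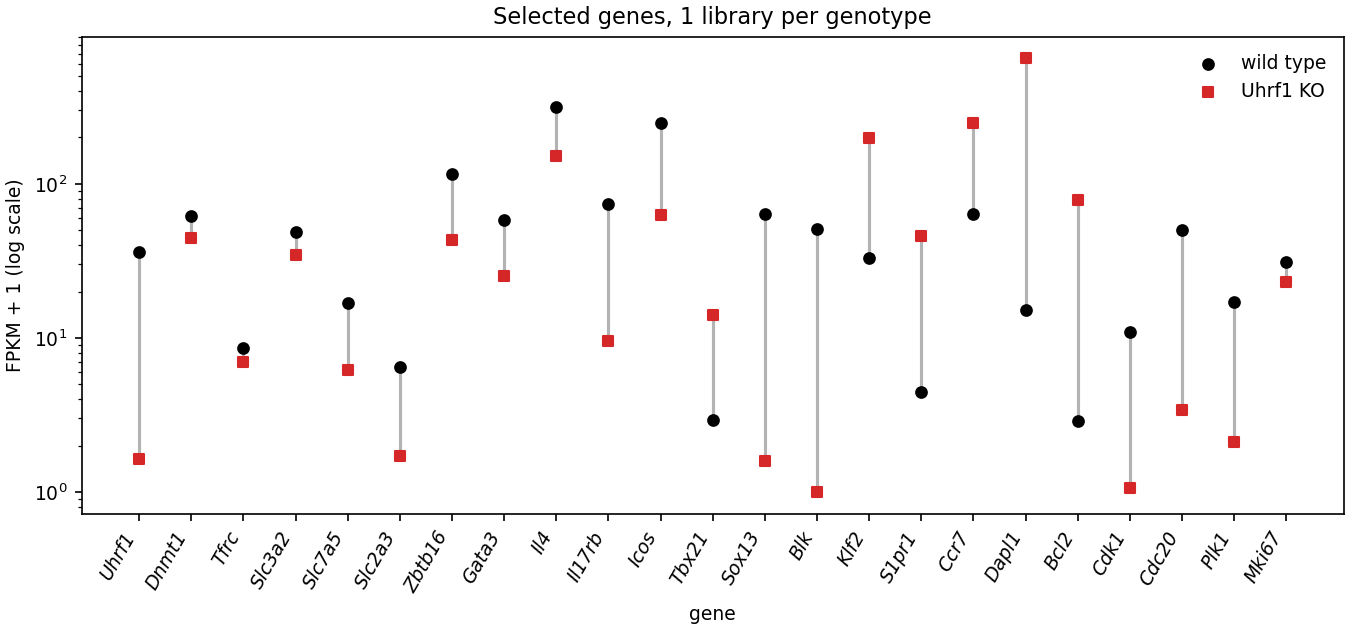
FPKM + 1 on a log axis for 23 named genes on the x axis, with the wild-type library as black circles, the Uhrf1 KO library as red squares and a grey line joining the pair. Uhrf1, Zbtb16, Il17rb, Sox13 and Blk are lower in the KO, and Tbx21, Klf2, S1pr1, Ccr7, Dapl1 and Bcl2 are higher.

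Genes of naive conventional T cells were higher in the KO as a group. Of 19 measured members 14 rose and 1 fell, and the median of 1.41 lay above all 10000 random lists. S1pr1, the receptor for thymic exit (chromosome 3, 115710433 to 115715055), rose from 3.48 to 44.9, 13.003-fold (interval 11.6 to 14.7). Klf2, a transcription factor of resting T cells, rose from 32.2 to 198, Ccr7 from 62.7 to 249 and Dapl1 from 14.1 to 651. The coreceptor genes had 92.3 and 105 for Cd4 and 237 and 367 for Cd8b1, named after their values were seen. Beside this rise, the 35 early iNKT and NKT2 genes, which share 2 measured genes with the list, had a median of -0.033, at percentile 33.7.

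FOXO targets were higher as a group, with 10 of 23 risen and 5 fallen (median 0.80, percentile 99.35). Foxo1 itself (chromosome 3, 52268337 to 52350109) rose from 6.73 to 41.7, 6.45-fold (interval 6.06 to 6.87). The list shares 5 measured genes with the naive T cell list; without them the median was 0.36, at percentile 85.1, inside the random range. Of 14 regulatory T cell genes 6 rose and 3 fell (median 0.75, percentile 98.9). Foxp3 rose from 0.227 to 2.63, on 20 and 102 reads at a locus of 4 genes (log2 ratio 0.55 with a pseudocount of 5), and Tnfrsf18 from 79.3 to 340. Among genes with a mean FPKM of at least 5 this median turned to -0.46. CD4 CD8 double-positive thymocyte genes had 3 risen and 8 fallen of 22 (median 0.05, mean -0.74, percentile 51.0). Cd24a, which marks immature thymocytes, fell from 15.5 to 0.142, and Arpp21 from 25.4 to 2.99.

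Of 25 genes of the DNA methylation machinery 4 fell, Uhrf1 included, and 1 rose (median -0.073, percentile 44.9). Dnmt1 had 61.1 and 43.6, Gadd45g fell from 3.51 to 0, Zbtb38 fell from 9.30 to 3.13, and the demethylation enzyme Tet1 rose from 0.196 to 1.96. With a pseudocount of 5 the log2 ratios of Gadd45g (-0.77), Zbtb38 (-0.81) and Tet1 (0.42) were short of the size rule. A list of germline genes, fixed as silenced by DNA methylation in somatic cells, was higher, with 7 of 10 risen and none fallen (median 1.18, percentile 99.1). Rhox2a (chromosome X, 37244992 to 37249690) rose from 0 to 18.9, at least 98.1-fold, and Syce1 from 0 to 7.77, at least 97.4-fold. Of the 36 germline genes in the files, 6 reached an FPKM of 1 in the wild type and 12 in the KO. Those 6 were not silent in the wild type, so the list does not measure loss of silencing alone. The germline call ended among genes with a mean FPKM of at least 5, at percentile 94.6, and allowing for the number of lists 5377 of 10000 draws held a departure as large. Markers of other cell types were higher in the same library, with medians of 2.42 for stromal, 2.56 for erythroid and 1.49 for myeloid genes.

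Imprinted genes, expressed from the copy of a single parent, were higher in the KO, with 10 of 19 risen and 3 fallen. Their median of 1.62 lay above all 10000 random lists. Nnat rose from 0 to 19.7, at least 151-fold, Peg12 from 0 to 12.7, at least 267-fold, Snrpn from 0 to 7.78, at least 211-fold, and Rasgrf1 from 0 to 6.59, at least 196-fold. Nnat and Snrpn each share their locus with another gene. Beside the rise of the imprinted list, genes of thymic epithelium and stroma, which share 1 measured member with it, had a median of 2.42. Among genes with more than 10 reads in each library, a limit chosen after the data were seen, the imprinted median was 0.42, at percentile 87.1. That limit leaves out by construction the members with no wild-type reads, such as Nnat, Peg12, Snrpn and Rasgrf1.

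Survival and stress genes gave single large changes inside lists that stayed within the random range. Bcl2, which blocks mitochondrial apoptosis (chromosome 1, 106538176 to 106714290), rose from 1.90 to 77.7, 40.9-fold in FPKM but 19.5-fold by scaled counts (interval 17.8 to 21.4, for the count fold only). It was the 1 named gene of 122 with reads in both libraries whose 2 folds differed by over 1.5 times. Casp6 fell from 34.5 to 1.44 and Bcl2a1b from 59.7 to 5.49. In the BCL2 family and caspases 3 rose and 9 fell of 24 (median 0.058, mean -0.38, percentile 60.9). Of 28 p53 targets 4 rose and 8 fell (median 0.017, mean -0.22, percentile 59.3). Cdkn1a, which encodes the cell cycle inhibitor p21, had 6.88 and 13.7, and Dcxr fell from 21.3 to 0. Of 13 heat shock and stress genes 4 rose and 1 fell (median 0.22, percentile 80.2). Hspb1 rose from 1.93 to 22.4.

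Signalling and cytokine lists were mixed. Of 29 genes induced early by the T cell receptor 6 rose and 10 fell (median 0.12, mean -0.11, percentile 66.6). Fos rose from 0.0918 to 25.6 and Cd69 from 6.74 to 43.4, while Dusp1 fell from 9.47 to 0.304. Of 40 interferon-stimulated genes 9 rose and 5 fell (median 0.26, percentile 88.3). Usp18 rose from 11.7 to 81.1 and Dhx58 fell from 23.8 to 6.53. Of 18 T cell cytokine and receptor genes 6 rose and 7 fell (median -0.44, percentile 9.12), but the list was apart with no filter (-0.69, percentile 1.365) and at a mean FPKM of at least 5 (-0.58, percentile 2.455). Il12rb1 fell from 27.0 to 0.529 and Il4ra rose from 4.07 to 29.6. Ifng had 39 and 0 reads, an FPKM of 0.844 and 0.

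Markers of cells other than T cells differed between the libraries too. Erythroid genes were higher in the KO, with 6 of 8 risen and none fallen (median 2.56, percentile 99.99). Hba-a1 rose from 60.7 to 428 and Car2 from 0.0344 to 35.1; globin genes are close copies, so single members are uncertain. Thymic epithelial and stromal genes had 6 of 9 risen and none fallen (median 2.42, percentile 99.95), with Col3a1 at 0.688 and 20.9 and Krt18 at 0.365 and 16.6. With no filter the stromal median was 0.29, at percentile 92.8, and the call ended. Of 16 myeloid and dendritic cell genes 9 rose and 4 fell (median 1.49, percentile 99.99). Over the alternatives run for it that median ran from 0.79 to 2.03, at percentile 99.98 or above. Apoe rose from 246 to 2677, while the neutrophil genes S100a8 and S100a9 fell from 86.4 to 0 and from 95.6 to 0.908. NK cell genes had 3 risen and 3 fallen of 6 (median 0.48, mean -0.20, percentile 78.9). B cell genes had 1 risen and 3 fallen of 7 (median -0.22, percentile 30.0), with Cd74 at 14.7 and 77.9 and H2-Ab1 at 22.3 and 6.14.

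**Figure D4:**
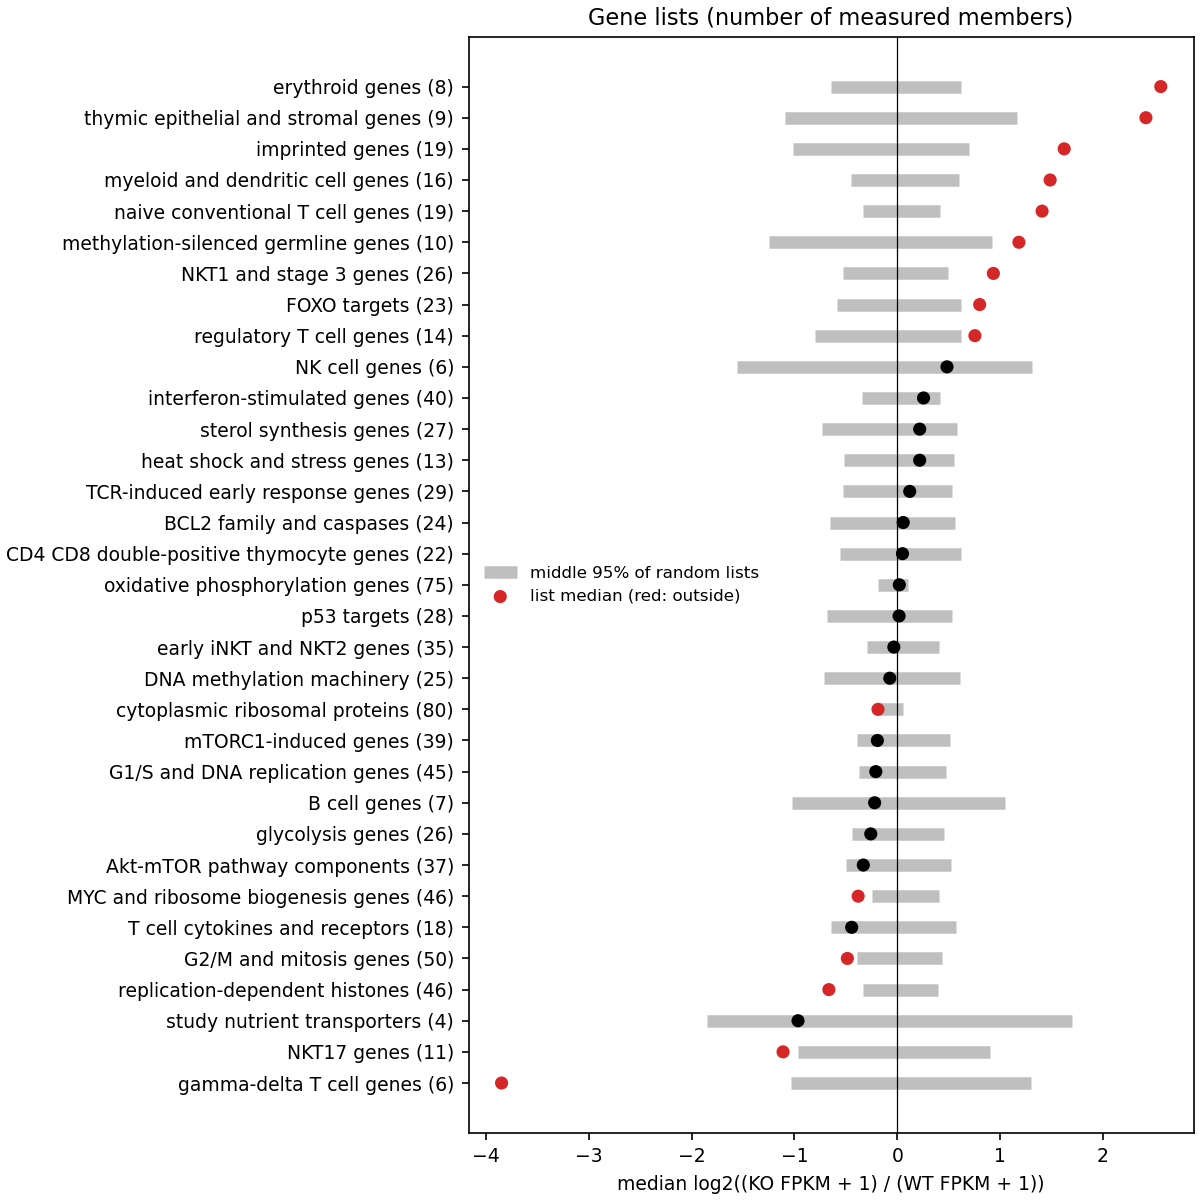
The x axis gives the median log2 ratio of KO over wild type for the 33 lists with at least 4 measured members, whose number stands in brackets on the y axis. Grey bars span the middle 95% of 10000 matched random lists; the 15 red points lie outside their bar, 9 of them on the high side and 6 on the low side.

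In all, 9 of the 33 lists lay above the range of random lists and 6 below it, where chance alone would put 1.65 lists outside. Allowing for the number of lists, a step chosen after the data were seen, departures as large as those of 8 lists arose in under 5% of draws: imprinted, histone, NKT1, naive T cell, gamma-delta, myeloid, stromal and erythroid genes. Some lists hold members with no reads in 1 library, whose ratio depends on the pseudocount. With such members set at 3 reads, the median log2 ratio of scaled counts was 1.43 for germline genes, 2.32 for imprinted genes, 1.01 for NKT1 genes, -1.20 for NKT17 genes and -4.90 for gamma-delta genes. It was -0.59 for G2/M genes, -0.75 for histones, 1.54 for myeloid genes and 2.49 for stromal genes. The mitochondrially encoded and T cell receptor segment lists had no member in the rows used and were not analysed here.

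The largest single rises were in genes with little or no signal in the wild type. Among genes with a mean FPKM of at least 5, the 10 largest rises were Grifin, Apobec2, Ptgds, Rab20, Npb, Apoc1, Sncg, Npy, Sst and Nupr1, of which 7 had no wild-type reads. Apobec2 had 1044 reads in the KO, at least 742-fold higher, and Ptgds, a prostaglandin D synthase, rose 95.5-fold (interval 70.1 to 134). The neuropeptide genes Npy and Sst had 216 and 192 KO reads. The 10 largest falls were S100a8, Lgals7, Rln3, Ly6d, Blk, S100a9, Macrod1, Trex1, Sox13 and Gzma, of which 7 had no KO reads. Trex1, a cytosolic DNA exonuclease, fell from 41.8 to 0 on 799 and 0 reads, at least 125-fold. Macrod1 shares its locus with another gene.

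Of the sex-linked list 2 genes were measured, too few for a percentile. Ddx3y had 7.66 and 8.98, and Eif2s3y rose from 15.7 to 38.4, both on the Y chromosome. Among members below the expression limit, the Y-linked genes Uty and Kdm5d went the other way, with 351 and 0 reads and 195 and 9 reads. Xist, transcribed from the inactive X chromosome, had 1 read in the wild type and 371 in the KO. The number and sex of the mice behind each library are not given in the sources used here, so a difference in the mice pooled or in the preparation is not separated from the genotype.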

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

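The 3 alternatives with more than 10 reads in each library, with a mean FPKM of at least 25 and without shared members were chosen after seeing the data. Uhrf1 kept its direction and its side of the size rule under all 11 alternatives run for it. The filters and the choice of row cannot change the ratio of a single gene, so only the other settings tested it. Of the 15 lists apart from random lists, 6 stayed apart under every alternative run for them: histones, MYC and ribosome biogenesis, naive T cell, gamma-delta, myeloid and erythroid genes. No alternative tests a difference between the preparations of the libraries. Among 1477 values of the 151 other named genes that passed the filter, 1457 kept their call and 0 reversed. Another 18 lost it, all at a pseudocount of 5, and 2 gained it, both for Rpl30. Many kept it by construction: 151 with no filter, 151 with the highest row and 96 with more than 10 reads in each library. The same holds for 116 at a mean FPKM of at least 5 and 58 at 25. The values that lost their call include Slc2a3 (-0.88), Myc (-0.88), Klrb1c (-0.87), Zbtb38 (-0.81), Gadd45g (-0.77), Slc2a1 (0.79), Foxp3 (0.55), Cd44 (0.52) and Tet1 (0.42). Upper-quartile scaling moved the median of all genes to -0.13, and list values under it are relative to that shift. Keeping the highest row per symbol moved nothing, since each symbol has 1 row. The filter on status and confidence limits was not run. No paired analysis was possible because each genotype has 1 library. For the changes given next the cause was not tested, except that stricter filters and size rules count fewer genes by construction.

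Rises numbered 1292 and falls 1254 at a pseudocount of 5, 851 and 1026 at a size rule of 2, and 467 and 328 at a mean FPKM of at least 25. Rises numbered 3332 at a size rule of 0.5. Falls numbered 1247 at a mean FPKM of at least 5 and 1504 with more than 10 reads in each library. With no filter the NKT1 median reversed to -0.025, cytokine genes became apart at -0.69, and the call was lost for imprinted genes (0.17), ribosomal proteins (-0.19), FOXO targets (0.36) and stromal genes (0.29). At a mean FPKM of at least 5 the regulatory T cell median reversed to -0.46, germline (0.996) and imprinted genes (0.61) lost their call, cytokine genes became apart (-0.58), and glycolysis (0.020) and TCR-induced genes (0.43) moved within the random range. At a mean FPKM of at least 25 the regulatory T cell median reversed to -0.73, G2/M genes lost their call (-0.14), and Akt-mTOR (-0.0165) and cytokine genes (-0.0029) moved. With more than 10 reads in each library germline (1.03), imprinted (0.42) and regulatory T cell genes (0.57) lost their call. That limit removes by construction the members with 10 reads or fewer in 1 library. The regulatory T cell call was also lost at a pseudocount of 5 (0.42). Without shared members FOXO targets (0.36) and NKT17 genes (-0.94) lost their call, NKT1 and regulatory T cell genes kept theirs, and too few gamma-delta genes were left for a value. Ribosomal proteins lost theirs under upper-quartile scaling (-0.33) and with the lowess trend removed (-0.0445), and oxidative phosphorylation genes moved to -0.12 under upper-quartile scaling. Counting of independent reads alone sent 2 of 9755 simulated unchanged genes past the size rule. Since PCR reads are not independent molecules, the simulation cannot show how far the number of molecules limits single genes.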

Other observations

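The tests on naive T cell and imprinted genes, the genes named in the next paragraph and Sparc were chosen after their values were seen; the 12 complexes and the bounds of the tests on the spread were written before.

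The libraries also differed in sex-linked genes. Xist, transcribed from the inactive X chromosome of females, had 1 read in the wild type and 371 in the KO (ratio 792, interval 141 to 31346), at a locus it shares with another gene. The Y-linked genes did not move together: Uty had 351 and 0 reads, and Kdm5d had 195 and 9, while Ddx3y had 2152 and 1305 and Eif2s3y 1291 and 1550. Y-linked reads in both libraries mean that each held RNA of male cells. Xist therefore does not tell the sex of the mice here, and an effect of the genotype on it was not tested. In the germline list Xlr4a, which was not silent in the wild type, had an FPKM of 85.6 there and 168 in the KO. Among imprinted genes H19 had 27.3 and 144.

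A first pattern was the wide spread of ratios, with an SD of 1.58 across 9955 genes. Counting error simulated for independent reads gave 0.06614 of the observed SD, and genes alone at their locus had 0.9972 of the SD of all genes. Neither such counting nor overlapping genes accounted for the spread. Subunits of 12 general complexes, which a cell makes together, had an SD of 1.04 over 254 genes against a mean of 1.35 for matched sets, a share of 0.7746 with a range of 0.683 to 0.886 over those sets; a share of at least 0.75 had been set beforehand as the mark of transcripts lost at random before amplification and against genotype alone. The value passes that bound but its range does not, and the demand that the range pass was added after the value was seen. By the rule set beforehand, the value alone would favour loss and exclude genotype as the sole source. The share cannot bear that reading, because transcripts of subunits need not change together in a knockout. Loss that struck all genes alike would leave complex genes as spread as matched ones. The SD of the 254 complex genes lay below the range of matched sets, 1.18 to 1.53. This argues against such loss as the sole source of the wider spread of the other genes, which were matched on mean FPKM only. The spread of the complex genes themselves could still come from loss. Of the 254 complex genes, 5 had 10 reads or fewer in the KO and 0 did in the wild type, the deeper library. Loss of transcripts and genotype cannot be told apart as sources with 1 library each, and both may contribute. A mixture of cells was not tested as a source of the spread.

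A second pattern was the rise of naive T cell genes (median 1.41). Its lowest percentile over all alternatives run for it was 100, and of 10000 draws of a random list for each of the 33 lists 1 held a departure as large in SDs, which argues against transcripts lost at random as the whole cause even though the list was picked among 33. With a lowess trend on expression removed, the naive T cell median was 1.329 at percentile 100. The random lists were already matched on expression, so this step could add little. Medians of all measured genes by expression bin ran only from -0.38 to 0.11. A trend of that size is too small to give a median of 1.41. Naive T cells in the sorted KO cells stay open. The 35 early iNKT and NKT2 genes fixed beforehand had a median of -0.03346, at percentile 33.7, with 10 fallen and 7 risen. That list shares 2 measured genes with the naive T cell list. Among its members Ccr7 rose from 62.7 to 249, while Icos fell from 247 to 62.0 and Il17rb from 72.8 to 8.61. A mixture could raise some members and lower others, so the median of this list cannot decide. An effect of genotype is untested beyond this and a candidate explanation beside a mixture; the sort gate was not analysed here.

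The last pattern was the rise of imprinted genes (median 1.62), the group in which loss of methylation is a biological explanation named by the genotype. Of the same 10000 draws 64 held a departure as large. Random loss of transcripts stays open, because 6 of the 19 measured members had no reads in 1 library. The call also ended at a mean FPKM of at least 5 (median 0.61, percentile 90.3) and with no filter (0.17, 95.8). With more than 10 reads in each library it ended too (median 0.42, percentile 87.1). That limit removes those 6 members by construction, so its outcome does not bear on loss. RNA from stromal cells stays open, since stromal genes had a median of 2.418, with Sparc at 9.82 and 56.8 and Col3a1 at 0.688 and 20.9, though with no filter their call ended too (0.29, percentile 92.8). The sources cannot be told apart from 1 library each, and DNA methylation was not analysed here.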
